A study of Mus musculus with 8 samples.

How the data were processed

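Total RNA of the soft tissue of the cochlea was measured on Affymetrix Mouse Genome 430 2.0 arrays, 1 array for each of 8 CBA/CaJ mice with the ears of a mouse pooled. Per the labels' protocols the mice were anesthetized with urethane (300 mg/kg) and perfused through the heart with saline to remove blood, RNA was isolated with TRIZOL and a spin column kit, and it was amplified and biotin-labelled with the Ovation system. The deposited values are linear intensities (MAS5 signals) per probe set, computed with MAS5 per the submitters' processing notes; the version of that software is not given in the sources used here. The authors scaled every array to a common level, since the mean of the deposited intensities without the lowest and highest 2% was 500.0 on each of the 8 arrays. No detection calls were used. The single file held 0 other columns of samples, and no array was left out.

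Gene names came from the platform annotation and were matched by Entrez identifier to current mouse gene symbols for 34754 probe sets, of which 0 changed their symbol. Of 45101 probe sets, 34945 named 1 gene, 932 several and 9224 none; the probe sets naming several genes or none were not used for genes. No genome build was named, so no coordinates are given. A gene was read by its probe set with the highest mean signal, with _x_at probe sets used where a gene had no other, as log2 of the signal (signals under 1 set to 1). Gene lists of 45 cell types, tissues and pathways (745 genes), the tests and the rule for named genes were set before the data were examined. Of these genes 81 had no probe set of their own in the tables used and were not analysed here. The genes named are the 20 with the highest mean signal (ribosomal proteins left out), the 20 with the largest SD among those whose probe sets agreed, and from each list the 4 detected members with the highest signal, the most variable detected member and up to 4 members not detected, with the sex-linked genes, the hemoglobin genes and Coch; some were left out for room. Mx1, Gfap, Sec14l3, Nefh, Thy1, Tsc22d3 and Zbtb16 are outside this rule and were chosen after their values were seen.

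The background threshold of an array was the 95th percentile of 149 probe sets of 116 genes, those of olfactory and vomeronasal receptors and of organs unrelated to the ear, and ranged from 43.3 to 72.6. Detected genes were above it on all 8 arrays. The share of detected members of each of 43 lists was compared with all other genes by a two-sided Fisher's exact test. The spread of a list was the median SD of its detected members, set against 10000 random lists of the same size matched on signal in 20 bins, which is a permutation of genes and not of mice (two-sided; the smallest possible p is 0.0002), and common variation was their mean pairwise Pearson correlation across mice, set against 10000 such lists (one-sided; the smallest possible p is 0.0001). Agreement of a gene's 2 brightest detected probe sets was tested by an exact permutation test of their correlation over all 40320 pairings of the mice. A list score was the mean deviation of members found in no other scored list, and the 136 pairs of 17 scores were tested in the same way, two-sided, with Pearson's r and Spearman's rho. All p-values were adjusted by Benjamini-Hochberg within each family, and 0.05 was the threshold. The labels call the arrays 8 replicates from 8 mice. The p-values of probe set pairs and score pairs take mice as units, and differences between mice include those of the assay. The p-values of the list tests rest on genes and do not account for differences between animals. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

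The tests were checked on simulated data made from the measured means of the 11593 detected genes, with lists of 15 members. Each probe set was given the median SD of probe sets of similar signal in place of its own. Apart from the changes set on purpose, noise was independent between genes. The simulation thus left out the scatter of SDs at a given signal and the variation that genes share on the real arrays. Rates of the spread, common variation and probe set tests may therefore not carry over to these arrays. The spread test called 10 of 10 lists whose spread was doubled and 9 of 10 at 1.5 times, and the test of common variation called 10 of 10 lists at a correlation of 0.5 and 10 of 10 at 0.25. Neither called any of 40 unchanged lists. The probe set test, on 5024 genes, recovered 70 of 200 genes with a shared correlation of 0.9 (35%) and called 8 of 4824 unchanged genes. Fisher's exact test called lists with 15 of 15 and with 3 of 15 members detected, but not lists with 10 of 15. Its p depends only on these counts, which were set in advance, so the 10 lists of each kind necessarily gave the same result.

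The alternatives were quantile normalization, scaling of each array to the same median of detected genes, log2 of the signal plus 32, the mean of all probe sets of a gene, leaving out _s_at and _x_at probe sets, the 99th percentile of the background, detection on at least 4 of 8 arrays, leaving out each replicate in turn, removal of the first principal component and Spearman correlation. A further alternative, removal of the trend along the signal of the hybridization controls, was chosen after seeing the data. For each gene named, each list with 5 or more detected members and each measure of array quality, the highest or lowest mouse was tested against the others with Dixon's criterion for 8 values at the 95% level.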

Results

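Gene expression was measured in the cochleae of 8 CBA/CaJ mice, an inbred strain used in hearing research as a standard with good hearing. The tissue was the soft part of the cochlea, which per the labels held the spiral ligament of the lateral wall, the organ of Corti with its hair cells, and the modiolus, the central core that holds the auditory neurons. The ears of each mouse were pooled and measured on 1 array, so the 8 arrays stand for 8 mice, and all of them form 1 group of normal cochlea. The labels give no treatment beyond the urethane anesthesia and saline perfusion of every mouse, and no sex, age or hybridization batch, so the data describe a profile and its variation between mice and hold no contrast between groups. On the array 34945 probe sets named 1 gene alone, for 18193 genes. Every value below is a signal in arbitrary units, given as the mean ± SD over the 8 mice (n = 8) or for 1 mouse by its number, which is only a name. Signals of different probe sets do not compare as amounts of RNA. The number of arrays limits the precision of each mean.

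The arrays' log2 signals correlated at r = 0.945 to 0.960 between any pair of arrays (across probe sets, which are not independent replicates), and 0 pairs of arrays held identical values. The first principal component held 36.2% of the variance, and mouse 1 lay apart on it with a loading of 0.82. Background thresholds ranged from 43.3 to 72.6. The number of genes more than 2-fold below the mean of the other arrays ranged from 5 (mouse 5) to 117 (mice 1 and 6). The number more than 2-fold above it ranged from 0 (mouse 7) to 100 (mouse 5). The ratio of 3′ to 5′ control signal, which rises when RNA is degraded, was 1.47 ± 0.0537 for Gapdh and 2.06 ± 0.144 for beta-actin (SD, n = 8). The Y-linked genes Eif2s3y (2781 ± 163), Kdm5d (354 ± 77.5) and Uty (230.2 ± 44.5) were above background on all 8 arrays. Xist, the RNA that silences 1 X chromosome in females, measured 50.1 ± 4.79, with a range of 44.2 to 58.5. It was above background on 5 of the 8 arrays. Its signals lay within the range of the thresholds, so this count does not show that Xist differed between mice.

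A gene was called detected when its signal exceeded the background threshold on every array, and 11593 of 18193 genes (63.7%) met this. A further 2183 genes exceeded it on some arrays only and 4417 on none. Of the 116 background genes (olfactory and vomeronasal receptors and genes of unrelated organs), 4 were detected (3.45%), namely Vmn2r29, Vmn2r84, Prm1 and Slc22a6, which are named here after their values were seen. The 20 genes with the highest signals, ribosomal proteins aside, were named by rule and included the galectin Lgals1 (20715 ± 2359), the prostaglandin D synthase Ptgds (16376 ± 2107), the ferritin heavy chain Fth1 (16287 ± 1599), the glutathione transferase Gsta4 (15906 ± 1355), the lipocalin Apod (15699 ± 1638) and the carbonic anhydrases Car3 (14542 ± 1119) and Car2 (12565 ± 1124). They also included 2 genes central to cochlear function: Coch (14226 ± 1333), which encodes the extracellular matrix protein cochlin and is mutated in a hereditary deafness, and Slc12a2 (13026 ± 1198), the sodium-potassium-chloride cotransporter of the strial marginal cells.

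Genes of the spiral ligament, the supporting cells and the stria vascularis were mostly detected. All 17 measured genes of spiral ligament and limbus fibrocytes were detected (adjusted exact p = 0.00548 in a two-sided Fisher's test against the other genes, 64.1% of which were detected). Besides Coch and Car3 they included otospiralin, Otos (12027 ± 1269), the cartilage matrix protein Ucma (10432 ± 1151) and pendrin, Slc26a4 (9863 ± 928), an anion exchanger mutated in Pendred syndrome. Of the supporting cell and tectorial membrane genes 18 of 20 were detected (adjusted exact p = 0.0417), including the matrix protein gene Epyc (11399 ± 723), the connexins Gjb2 (10282 ± 973) and Gjb6 (9602 ± 915) of the cochlear gap junction network, and Fbxo2 (8442 ± 817). The tectorial membrane gene Tectb was detected (242 ± 75.9), whereas the probe set of Tecta stayed below background on all arrays (10.5 ± 4.53). In the stria vascularis, which secretes endolymph, 10 of 12 marginal cell genes, 11 of 15 intermediate cell and melanocyte genes and 5 of 5 basal cell genes were detected, shares that did not pass the test (adjusted exact p = 0.312, 0.673 and 0.245). Marginal cell genes included Esrrb (3947 ± 453) and the potassium channel subunit Kcne1 (3429.7 ± 649); intermediate cell genes included the melanin synthesis gene Dct (10872 ± 1228), Mitf (7853 ± 618) and the potassium channel Kcnj10 (5531 ± 847), which the endocochlear potential depends on; basal cell genes included Cldn11 (5964 ± 721).

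Hair cell genes were detected no more often than other genes. Hair cells are few in this tissue, and 12 of 19 of their genes were detected (adjusted exact p = 1, Fisher's test). Detected members included the myosin gene Myo6 (4338 ± 339.8), Lhfpl5 (671 ± 69.7) of the mechanotransduction complex, Ush1c (549 ± 72.1) and otoferlin, Otof (503 ± 108), which acts in vesicle release at the hair cell synapse. Signals of the transcription factor Pou4f3 (12.1 ± 8.97) and of the tip link cadherin Cdh23 (16.7 ± 8.22) were below background on every array, and the channel gene Tmc1 (66.9 ± 10.9) was above it on 7 of 8. Neuronal genes of the spiral ganglion were detected for 20 of 23 members (adjusted exact p = 0.0588), among them Snap25 (7957 ± 1422), Stmn3 (4391 ± 1198), the neurofilament Nefl (4127 ± 1277) and the calcium-binding protein Calb2 (3897 ± 965). Of the Schwann cell and myelin genes 13 of 15 were detected (adjusted exact p = 0.193), including S100b (12211 ± 1220.0), Pmp22 (7654 ± 785) and Mbp (7430.3 ± 1335). Of the vestibular organ and otoconia genes 3 of 5 were detected (adjusted exact p = 1). Genes of hereditary deafness as a class were detected more often than other genes, at 43 of 53 (adjusted exact p = 0.0310).

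Genes of ion and water transport were detected at shares from 4 of 11 to 8 of 9 per family. Of the Na,K-ATPase and NKCC genes 8 of 9 were detected, including Atp1b1 (10624 ± 1044), and of the potassium channels 14 of 18, including Kcnj16 (6247 ± 323) and Kcnk1 (6112 ± 414). Connexins were detected for 6 of 11 genes, with Gja1 (2677 ± 705) beside Gjb2 and Gjb6. Of the 11 measured aquaporins, the 4 detected were Aqp1 (3175 ± 584), Aqp4 (1506 ± 364), Aqp5 (1032 ± 189.8) and Aqp11 (478 ± 57.1). Tight junction genes were detected for 16 of 19 members and sodium channel and calcium transport genes for 8 of 14, including the calcium pump Atp2b1 (4119 ± 128). None of these 6 families passed the test, with adjusted p values from 0.132 to 0.673 in Fisher's exact tests.

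Every measured glucocorticoid-responsive, heat shock and antioxidant gene was detected, while most cytokines were not. All 14 glucocorticoid-responsive genes were detected (adjusted exact p = 0.0162), including the kinase Sgk1 (8641 ± 865), and so were all 12 heat shock genes (adjusted exact p = 0.0252), such as Hspa8 (12603 ± 1253), and all 17 antioxidant enzyme genes (adjusted exact p = 0.00548), such as Sod1 (12450 ± 1019.9). Interferon-stimulated genes were detected for 15 of 16 members (adjusted exact p = 0.0417), circadian clock genes for 16 of 17 (adjusted exact p = 0.0310), including Nr1d2 (4622 ± 378), and reference genes for 10 of 10 (adjusted exact p = 0.0417). The glucocorticoid receptor Nr3c1 (2792 ± 122) and Hsd11b1 (3477 ± 364), which regenerates active glucocorticoid, were detected within a list of hormone receptors of which 9 of 14 were. Cytokine and chemokine genes were detected less often than other genes, at 9 of 23 (adjusted exact p = 0.0417). Mif (5580.1 ± 1121), Tgfb2 (3622 ± 350.3) and Cxcl12 (2025 ± 231) were detected, while Il6 (9.41 ± 7.94) was below background on every array and Il1b (78.7 ± 25.7) above it on 6. Lists that did not pass the test were the hormone receptors, innate immune receptors (11 of 16), complement (8 of 9), immediate early genes (17 of 21) and neurotrophins with glutamate receptors (7 of 16), with adjusted p from 0.194 to 1 in Fisher's exact tests.

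Genes of other tissues that a dissected ear can hold fell on both sides. Macrophage genes (18 of 19, adjusted exact p = 0.0162) and genes of collagens and basement membrane (23 of 24, adjusted exact p = 0.00548) were detected more often than other genes, with Lyz2 (3277 ± 897), Cd74 (1409 ± 276) and the collagen gene Col1a2 (2726 ± 659.9) among them. Detected less often were genes of T and natural killer cells (1 of 12, adjusted exact p = 0.00398), of middle ear and airway epithelium (2 of 14, adjusted exact p = 0.00398), of erythroid cells (2 of 12, adjusted exact p = 0.00760), of B lymphocytes (3 of 14, adjusted exact p = 0.00861), of skeletal muscle (7 of 20, adjusted exact p = 0.0310) and of the central nervous system (7 of 19, adjusted exact p = 0.0417). The single member detected among T and natural killer cell genes was Cd2 (334 ± 65.9). Neutrophil and myeloid precursor genes (5 of 15, adjusted exact p = 0.0588) and bone (9 of 11 osteoblast and 5 of 11 osteoclast genes), cartilage (10 of 15), endothelial (11 of 13), pericyte (10 of 11) and proliferation genes (6 of 13) did not pass the test, with adjusted p up to 1. In all, 11 of the 43 lists were detected more often and 7 less often than the other genes, and 4 of these 18 kept their call under all 15 alternatives, namely the fibrocyte, antioxidant, T and natural killer cell, and airway epithelium lists. Requiring the threshold on at least 4 of 8 arrays in place of all left 7 lists. Many genes of blood, marrow and muscle were above background in some mice only, and 8 of 12 erythroid genes, 13 of 15 neutrophil genes and 11 of 20 muscle genes were then detected.

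**Figure D1:**
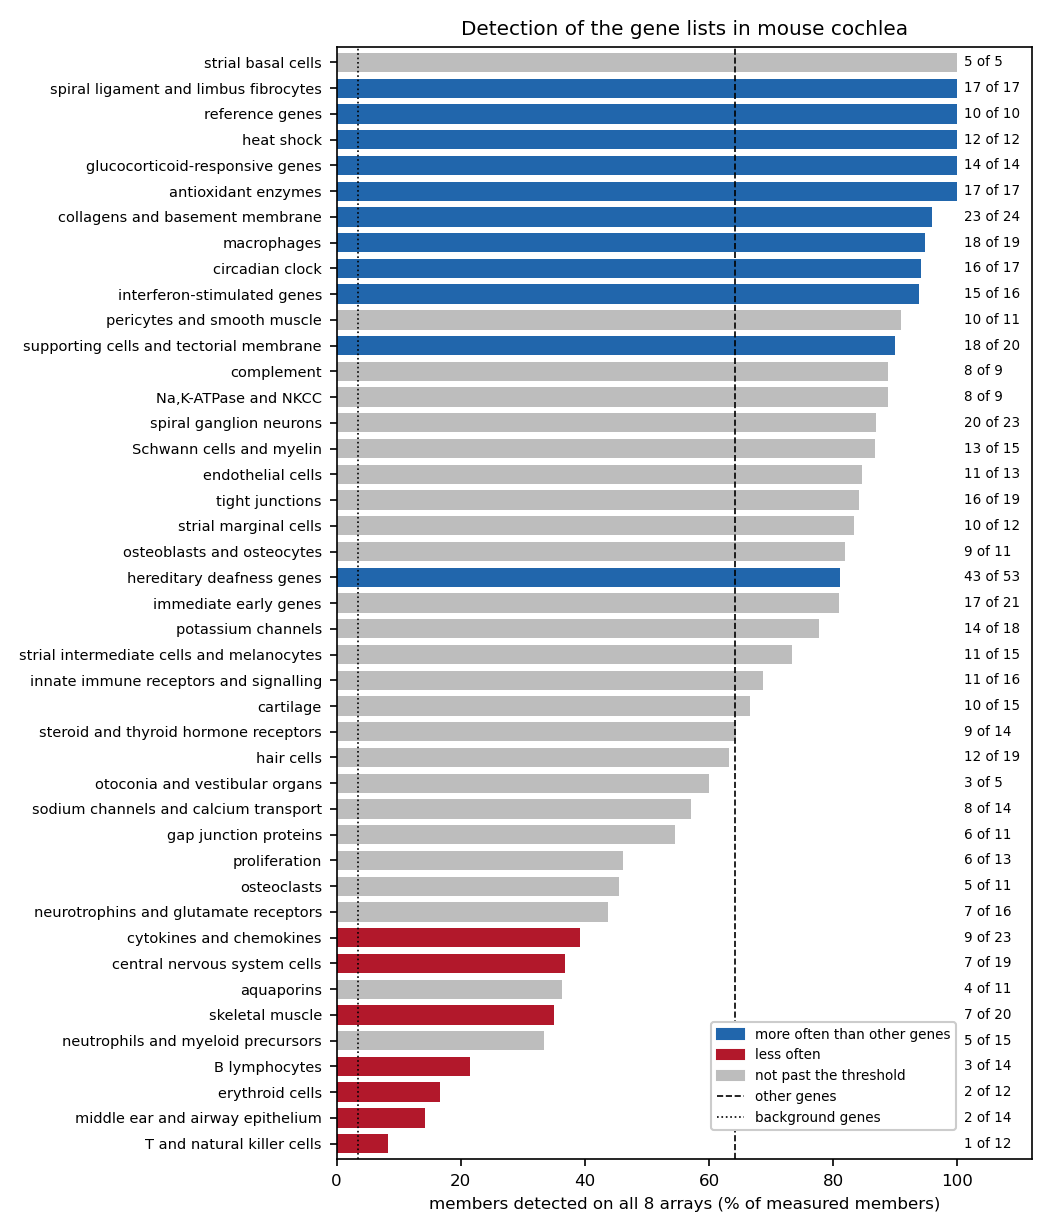
Share of each list's measured members detected on all 8 arrays, in percent, with the counts at the right; blue lists were detected more often and red lists less often than the other genes (Fisher's exact test, adjusted), and grey lists did not pass. The dashed line marks the other genes (64.1%) and the dotted line the background genes (3.45%); all 17 fibrocyte genes were detected and 1 of 12 genes of T and natural killer cells.

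Most genes differed little between the mice, and a few groups differed a great deal. The median SD of the detected genes was 0.18 on the log2 scale. It exceeded 0.5 in 332 genes and 1 in 37. Of the 37 lists with at least 5 detected members, 10 had a larger spread between mice than random lists of the same size and signal, and 0 a smaller one. Members of 11 lists rose and fell together across the mice, and 8 lists passed both tests. Cochlear lists such as the fibrocytes (median SD 0.15 against 0.13 in random lists, adjusted permutation p = 0.392), supporting cells (median SD 0.18, adjusted permutation p = 0.235), marginal cells (0.16, 0.619) and hair cells (0.29, 0.155) did not pass. Common variation of the hair cell genes did not pass (adjusted permutation p = 0.0580) but did under 10 of 18 alternatives. The p-values come from 10000 random lists and describe these 8 arrays, since genes are not independent replicates. For 6 of the 10 lists with a larger spread, p was 0.0002, the smallest they can give.

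Neuronal genes were the most variable group among the cochlear cell types, and they were low in mouse 6. Nefl measured 1741 in mouse 6 and 3636 to 6059 in the other mice, Snap25 4960.5 against 7257 to 9451, and the neurofilament Nefm 333 against 875 to 1707. Of the 23 measured neuronal genes, 16 had their lowest value in mouse 6 and 13 their highest in mouse 1. Mouse 1 was the highest mouse for 33.7% of all detected genes and mouse 6 for 9.57%. Of 19 central nervous system genes 4 were highest in mouse 1 and 7 in mouse 6, and 7 of the 19 were above background on no array. Of 45 genes of unrelated organs 5 were highest in mouse 1 and 11 in mouse 6, but 38 of the 45 were above background on no array. In mice 1 and 6 the 7 detected central nervous system genes had a mean deviation of 0.65 and 0.82 (log2). Their median deviation from the other mice was -0.02 and 0.11. These 7 leave out Mog and Olig1, which were above background on 2 arrays only, those of mice 1 and 6. The neuronal list's spread (median SD 0.47 against 0.17 in random lists, adjusted permutation p = 0.00123) and the correlation among its members (mean r 0.54 against 0.00, adjusted permutation p = 0.000925) passed both tests under every alternative run. Other neuronal genes with a wide spread, picked by the agreement of separate probe sets, followed the same mouse: Vsnl1 was 323 in mouse 6 and at least 830.1 elsewhere, Map1a 311 and at least 617, and Serpini1 347 and at least 749.6. Potassium channel genes passed the spread test (median SD 0.23 against 0.16 in random lists, adjusted permutation p = 0.0266); their most variable member was the neuronal channel Kcnc1, lowest in mouse 6 at 302 against 556 to 1015. That call ended under 4 of 17 alternatives, among them without mouse 1 (adjusted permutation p = 0.217). Schwann cell genes varied together (mean r 0.29 against -0.01, adjusted permutation p = 0.0106) except without mouse 3 (adjusted permutation p = 0.0964), and their spread did not pass (adjusted permutation p = 0.0545) but did under 12 of 17 alternatives.

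Neutrophil genes had a wide spread, much of it from mouse 7, and the 5 detected ones were lowest in mice 7 and 1. S100a8, a calcium-binding protein abundant in neutrophils, measured 528 in mouse 7 and 1759 in mouse 1, and 3659 to 9220.2 in the other 6. The granule protein genes Camp (72 in mouse 7, 372 in mouse 1, 519 to 2010 in the others) and Ngp (57.5, 264 and 608 to 1469) followed. The 5 detected members moved almost as 1 (mean r 0.98 against -0.05, adjusted permutation p = 0.000925), with a large spread (median SD 1.37 against 0.15 in random lists, adjusted permutation p = 0.00123). Without mouse 7 the median SD fell to 0.85. Of all 15 measured members, including the myeloperoxidase gene Mpo (31.1 in mouse 7 and 1014 in mouse 3), 12 were lowest in mouse 7. Precursor genes were also low in mouse 8, where Mpo measured 103 against 164 in mouse 1. Erythroid genes were lowest in the same mouse for 9 of 12 members. The beta-globin gene Hbb-b2 measured 1254 in mouse 7 and up to 9512 elsewhere (its near-identical paralogs can bind the same probes), and the red cell anion exchanger Slc4a1 38.4 and up to 1784. Cell division genes were low in mice 7, 1 and 8: Birc5 measured 69.4, 128 and 125 in these and 197 to 658 in the others. Of 13 proliferation genes 6 were lowest in mouse 7, and the list passed both tests (median SD 0.81 against 0.24 in random lists, adjusted permutation p = 0.00123; mean r 0.59 against 0.00, adjusted permutation p = 0.00296).

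Bone and macrophage genes were on average highest in mice 3, 5 and 6. The bone collagen gene Col1a1 measured 2234, 3335 and 2867 in these mice and at most 976 in the others. Its relative Col1a2, which is also made by fibrocytes, ranged from 1737 to 3883, the bone sialoprotein gene Ibsp from 343 to 1818, and the osteoclast phosphatase Acp5 from 66 to 336. Osteoblast and osteocyte genes passed both tests (median SD 0.35 against 0.18 in random lists, adjusted permutation p = 0.00423; mean r 0.53 against 0.01, adjusted permutation p = 0.00678), as did osteoclast genes (median SD 0.75 against 0.23 in random lists, adjusted permutation p = 0.00123; mean r 0.50 against 0.03, adjusted permutation p = 0.0323) and macrophage genes (median SD 0.30 against 0.22 in random lists, adjusted permutation p = 0.0222; mean r 0.26 against 0.03, adjusted permutation p = 0.0125). The macrophage list was led in spread by Pf4, a chemokine gene of platelets and megakaryocytes, at 241 to 1638. The correlation among osteoclast genes did not pass without mouse 4 (adjusted permutation p = 0.0588) or mouse 5 (0.138), and that among macrophage genes without mouse 4 (0.0601) or at the stricter background (0.177). Collagen and basement membrane genes varied together (mean r 0.21 against 0.03, adjusted permutation p = 0.0237), though not without mouse 8 (adjusted permutation p = 0.129) nor at the stricter background (0.132).

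Mouse 5 stood apart in genes of skeletal muscle and of airway-type epithelium. Mylpf, a myosin light chain of fast muscle, measured 3034 in mouse 5 and at most 263 in the others, and the skeletal actin gene Acta1 822 and at most 29. Of 20 measured muscle genes 16 were highest in mouse 5. Of 14 epithelial genes 13 were, including the mucin Muc16 (247 and at most 28.7), Foxj1, a regulator of ciliated cells (131 and at most 19.5), and the secreted protein gene Bpifa1, which was detected in every mouse (18387 in mouse 5, 1079.9 to 7395 in the others). The 7 muscle genes detected on all arrays passed the spread test (median SD 0.64 against 0.22 in random lists, adjusted permutation p = 0.00123) and varied together (mean r 0.38 against 0.00, adjusted permutation p = 0.0201). The correlation among them ended without mouse 5, where the mean r was -0.03 (adjusted permutation p = 0.690), and with Spearman correlation (0.166). The muscle list also held Pvalb (5411 ± 1114), a calcium-binding protein that spiral ganglion neurons express as well, and its value was lowest in mouse 6 (3142).

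Interferon-stimulated genes varied widely and were highest in mouse 8. Ifit1 measured 7845 in mouse 8 and 950.5 to 3688 in the others, the antiviral gene Rsad2 4686 against at most 1144, and the chemokine Cxcl10 1643 against at most 244. Of the 16 measured members 13 were highest in mouse 8. Mice 2 and 5 held the next values of Ifit1 (3389 and 3688) and of Ifit3 (2939 and 3726), while mouse 4 had the lowest Ifit3 (767). The list passed the tests of spread (median SD 0.86 against 0.20 in random lists, adjusted permutation p = 0.00123) and of common variation (mean r 0.75 against 0.03, adjusted permutation p = 0.000925) under every alternative run. Outside the list, the interferon-induced GTPase genes Iigp1 (1739 in mouse 8 against at most 591) and Gbp6 (2152 against at most 1737) had the same highest mouse, while Rtp4, also interferon-induced, was highest in mouse 2 (2000.3, and 1732 in mouse 8).

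Heat shock genes varied together, and some were lowest in mouse 1. The inducible heat shock gene Hspa1b measured 1647 in mouse 1 and 3419.6 to 8885 in the others, and the related Hspa1a 81.6 and 122 to 548; these paralogs are nearly identical in sequence. Of 12 heat shock genes 5 were lowest in mouse 1 and 5 in mouse 6, and mouse 1 was lowest for 23.9% of all detected genes. Common variation of the list passed (mean r 0.52 against 0.05, adjusted permutation p = 0.000925), and the mean r was 0.27 to 0.67 under the alternatives. The list's spread did not pass (median SD 0.17 against 0.13 in random lists, adjusted permutation p = 0.171) but did under 4 of 17 alternatives. Glucocorticoid-responsive genes had a larger spread (median SD 0.23 against 0.14 in random lists, adjusted permutation p = 0.00925) without common variation (adjusted permutation p = 0.167), and their most variable member was Lcn2 (147 to 1376), which is also a neutrophil gene. That spread did not pass without mouse 2 (adjusted permutation p = 0.0540) or mouse 6 (0.208). Depp1, a target of FoxO transcription factors, was lowest in mouse 1 at 135 against 561 to 1372. Immediate early genes, which respond to handling within minutes, did not pass in spread (adjusted permutation p = 0.0678) or common variation (0.0945), though the spread passed under 9 of 17 alternatives. Circadian clock genes passed neither (adjusted permutation p = 0.235 and 0.796). Egr1 was 2539 ± 573 and the clock gene Per2 320.4 ± 121, with its highest value in mouse 7 (528).

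**Figure D2:**
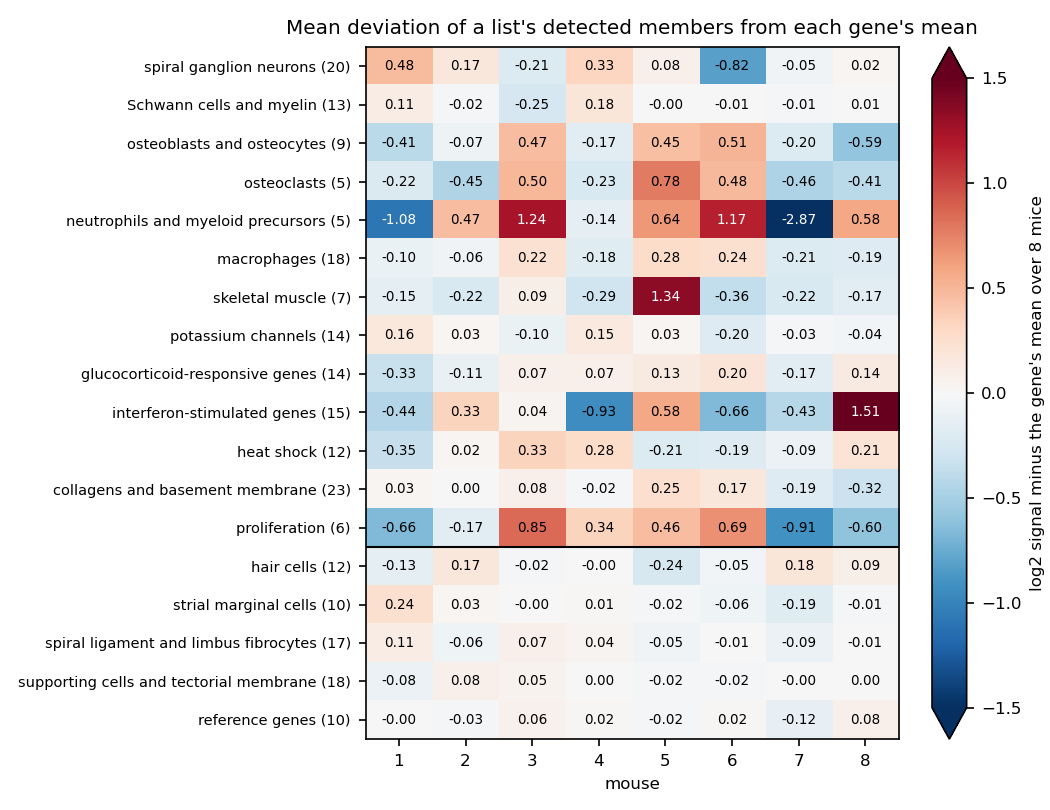
Mean log2 deviation of each list's detected members (number in brackets) from each gene's mean over the 8 mice, for the 13 lists that passed either test and, below the line, 5 lists that did not. Values range from -2.87 for neutrophil genes in mouse 7 to 1.51 for interferon-stimulated genes in mouse 8, and neuronal genes reach -0.82 in mouse 6.

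Differences between mice could be read from separate probe sets of a gene in a minority of genes. The adipocyte fatty acid binding protein gene Fabp4 had the largest spread among them (5517 in mouse 5, 88.6 to 914 in the others), and its probe sets correlated across the mice at r = 0.98 (adjusted p = 0.0212, one-sided exact permutation test over 40320 pairings). So did those of Col1a1 (r = 0.96, adjusted p = 0.0137), of the ribonucleotide reductase gene Rrm2 (r = 0.99, adjusted p = 0.0119), of Hspa1b (r = 0.99, adjusted p = 0.0119) and of Nefl (r = 0.97, adjusted p = 0.0196), in exact permutation tests. Of 5024 genes with at least 2 detected probe sets, 554 (11%) passed. Of as many pairs drawn from different genes 0 passed. The drawn pairs were adjusted on their own and so met another cutoff of p, and 0 is not the chance count for the 554. The median r was 0.34, against 0.02 for the drawn pairs. Among the 75 genes with an SD over 0.5, 37 passed. Of the 164 such genes in the fixed lists, 36 passed over all genes and 55 when adjusted over the list alone; for the neuronal list these were 5 and 5 of 8, and for collagens 6 and 8 of 14. Separate probe sets can share cross-hybridization or lie in different transcripts. An unadjusted p under 0.05 in the exact permutation test arose in 29.9% of the 5024 genes and in 11.9% of the drawn pairs. The count fell to 86 without mouse 1 and to 179 without probe sets that can bind several transcripts.

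Whether whole cell types rose and fell together could not be settled with 8 mice. Mice with higher osteoclast scores had higher macrophage scores (r = 0.95, exact permutation p = 0.00419; rho = 0.83, exact permutation p = 0.0154; adjusted p = 0.248 and 0.380), and r was 0.90 without the 2 mice farthest from the median osteoclast score. Neutrophil and erythroid scores ran together likewise (r = 0.82, exact permutation p = 0.00546; rho = 0.90, exact permutation p = 0.00456; adjusted p = 0.248 and 0.310), with r = 0.54 without the 2 mice farthest from the median. The erythroid score rested on only 2 genes and the neutrophil score on 5. Of the 136 pairs of 17 list scores, 0 passed after adjustment by Pearson's r and 0 by Spearman's rho. At an unadjusted p under 0.05 in the two-sided exact permutation test, 16 pairs passed by r and 15 by rho. By chance 6.80 would pass if the scores shared no array-wide variation. Probe set pairs drawn from different genes, however, reached a p under 0.05 in 11.9% of cases (one-sided exact permutation test). The value of 6.80 is therefore not the chance count on these arrays, and the 16 and 15 pairs show no excess by it. No batch was given by the labels, so no pair could be recomputed within batches.

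**Figure D3:**
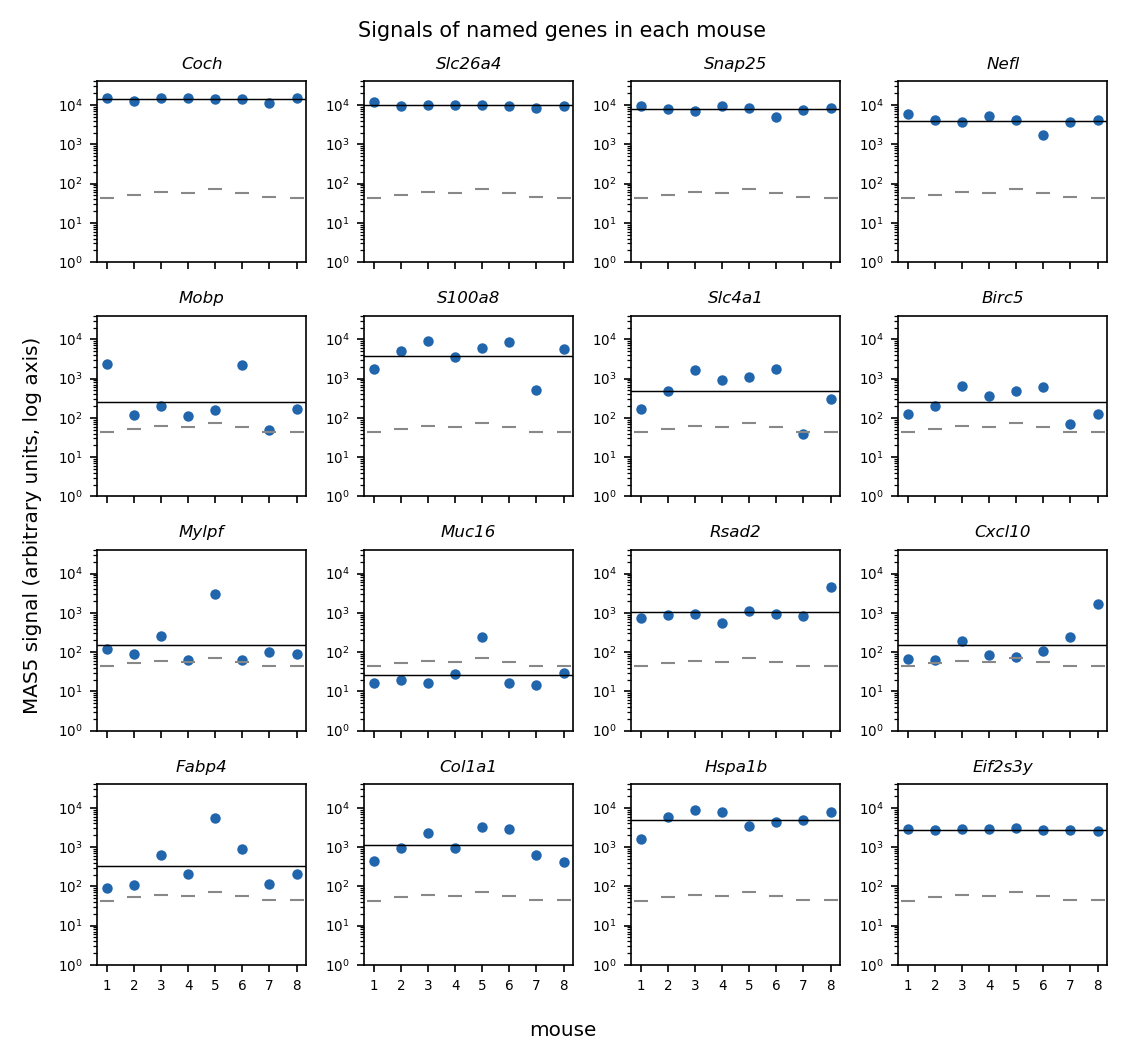
Signal of 16 genes in each of the 8 mice (points, logarithmic axis), with the mean of the log2 signals (line) and the background threshold of each array (grey dashes). Coch and Slc26a4 hardly differ between mice, Nefl is lowest in mouse 6 (1741), S100a8 in mouse 7 (528), and Mylpf is highest in mouse 5 (3034).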

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

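The tests of the hybridization control trend and of degraded RNA were set before their result was seen, and the other tests of explanations here after. No biological explanation from the design was tested, because the 8 mice form 1 group.

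In 32 of 168 values tested, 1 mouse lay farther from the rest than 95% of samples of 8 would show; chance alone gives about 1 in 20, or 8.40. These counts do not compare, since genes named for their spread or after their values were seen are among them. Of 281 genes that the naming rule picks without regard to spread, 41 met the same criterion (14.6%), and of all detected genes 12.6%. Mouse 1 had the highest value, apart from the others, of Atp2b1 (4398, others at most 4167), Bsnd (235, others at most 132), Kcne1 (4906, others at most 3565), Mif (8198, others at most 5775), Tgfb2 (4413, others at most 3676) and Ucma (13106, others at most 10418). It was lowest for Depp1 (135, others at least 561), Kdm5d (182, others at least 308) and Tsc22d3 (483, others at least 1100.2). Mouse 5 was the highest for Acta1 (822, others at most 29), Lpl (2243, others at most 624), Muc16 (247, others at most 28.7), Mylpf (3034, others at most 263), Sec14l3 (2106, others at most 25.9) and Thrsp (1805, others at most 465). Mouse 6 was the lowest for Nefh (1497, others at least 3429), Nefl (1741, others at least 3636), Nefm (333, others at least 875), Pvalb (3142, others at least 4743), Serpini1 (347, others at least 749.6), Snap25 (4960.5, others at least 7257), Thy1 (302, others at least 776) and Vsnl1 (323, others at least 830.1). Mouse 8 was the highest for Cxcl10 (1643, others at most 244), Mx1 (1527, others at most 192) and Rsad2 (4686, others at most 1144). Alas2 was lowest in mouse 7 (16.3, others at least 110.5). Mal was highest in mouse 4 (4659.5, others at most 4233). Olig2 was lowest in mouse 8 (4.70, others at least 15.2), but it was below background on all 8 arrays. Nefh, Thy1, Sec14l3, Mx1 and Tsc22d3 were chosen after their values were seen. Among lists the mean log2 deviation stood apart for skeletal muscle genes in mouse 5 (1.34) and cytokine and chemokine genes in mouse 8 (0.50); the median deviation of the cytokine and chemokine genes from the other mice was 0.04, with 5 members above and 4 below. On the array level, mouse 1 stood apart on the first principal component, with a loading of 0.82.

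Neutrophil genes were low in mice 1 and 7. A trend along the hybridization control signal as the whole cause is argued against: with that trend removed, the mean pairwise r of the neutrophil list was 0.982 (adjusted permutation p = 0.00123). Circulating blood left after perfusion as the only source was not decided. Across mice, 16 genes of marrow precursors and cell division correlated with S100a8 and S100a9 with a median r of 0.801. The 95th percentile of random lists was 0.207. The 6 precursor genes (r of 0.648 to 0.936) belong to the neutrophil list. That list and the cell division genes had already been seen low in mouse 7, so the correlation partly restates the pattern. For 3 DNA replication genes r was only 0.104 to 0.220, and in mouse 8 Mpo was low (103) while S100a8 was not (5552). Bone marrow carried along with bone in varying amounts stays open: the osteoblast score followed the neutrophil score with r = 0.518 (exact permutation p = 0.193; rho = 0.71, exact permutation p = 0.0576; r = 0.23 without the 2 mice farthest from the median), which 8 mice cannot decide.

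Muscle and airway epithelium genes were high in mouse 5. A general rise of low signals on this array, which had the highest background threshold, is argued against: 85.3% of the 34 members were highest in mouse 5 (95% exact interval 68.9 to 95), against 15% of 6575 other genes not detected on all arrays (14.1 to 15.9). Tissue from outside the cochlea, such as middle ear muscle and mucosa, stays open: 85% of the muscle genes and 85.7% of the epithelial genes were at least 2 times higher in mouse 5 than the median of the others, against 6.27% of all genes. That test was set after these lists were seen to be high in mouse 5, so it restates the pattern and decides nothing. Bpifa1 was above background in every mouse.

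Neuronal genes were low in mouse 6. Loss of the spiral ganglion together with its glia to the same degree is argued against, while a smaller loss of glia stays open. The median deviation of Schwann cell genes lay 0.98 (log2) above that of neuronal genes, which was -1.05. Exact 95% intervals were -1.36 to -0.70 for neuronal genes and -0.20 to 0.11 for Schwann cell genes. These intervals take genes of 1 array as independent, which they are not, and hold no spread between mice. The median of 5 glial genes with a role in peripheral nerve was -0.11 (Drp2 -0.30, Pmp22 -0.25, S100b -0.11, Ncmap -0.06, Egr2 0.05). All 5 lay above the neuronal interval, though Pmp22 was lower in mouse 6 (6453) than in any other mouse. The Schwann cell list also holds genes of central myelin, such as Mbp. Mbp (9286) and the oligodendrocyte gene Mog (356) were high in mouse 6. Central myelin could thus hide part of a loss of Schwann cells, and the list alone cannot exclude one. Dilution by other RNA is argued against too, as the median of 68 hair cell, strial, fibrocyte and supporting cell genes lay 1.01 above the neuronal median. RNA degradation is argued against by the 3′ to 5′ ratio of Gapdh, 1.39 in mouse 6 and 1.41 to 1.54 in the others, and of beta-actin, 1.86 and 1.88 to 2.23. A smaller share of neuron cell bodies in the dissected tissue and a difference between animals stay open and were not tested. Of 19 central nervous system genes, 7 were highest in mouse 6 and 4 in mouse 1 (mean deviation of the 7 detected 0.82 and 0.65, median 0.11 and -0.02). The 7 detected genes leave out Mog and Olig1, which were above background in mice 1 and 6 only. Of 45 genes of unrelated organs, 11 were highest in mouse 6 and 5 in mouse 1. Since 38 of these 45 were above background on no array, their highest mouse says little, and the counts ignore the size of a difference.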

How the results depend on the processing

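The number of genes detected on all 8 arrays stayed between 9036 and 12665 over the 15 alternatives, against 11593. The number of lists detected more or less often than other genes was 18, fell to 7 with detection on at least 4 of 8 arrays, a rule that by its construction admits genes present in some mice only, and lay between 17 and 20 without 1 replicate. Lists whose members vary together numbered 11, fell to 5 at the 99th percentile of the background, where fewer lists kept 5 detected members, and rose to 17 with the first principal component removed; the cause of this rise was not tested. Lists with a larger spread numbered 7 to 15, against 10. Lists left with fewer than 5 detected members gave no value. Genes whose probe sets vary together numbered 554, and 179 without _s_at and _x_at probe sets (4202 genes tested, 165 of the calls shared), 257 with Spearman correlation (240 shared), and 86 to 385 without 1 replicate, where 5040 pairings remain and the smallest p is 0.000198; the lowest came without replicate 1. Pairs of correlated list scores stayed at 0 under all alternatives run. Of single lists, 4 of 18 detection calls, 8 of 10 spread calls and 6 of 11 calls of common variation held under every alternative that gave a value. Of lists that did not pass, 5 passed in detection, 6 in spread and 7 in common variation under at least 1 alternative. Among list results that passed in the main run or under the alternative compared, 1 turned in direction, the mean r of skeletal muscle genes. It was 0.38 with all mice and -0.0317 to 0.456 without 1 replicate. The lowest value came without replicate 5 and did not pass (adjusted permutation p = 0.690), so it shows no opposite correlation. Lists that passed in neither were not checked for direction. The trend along the hybridization controls, an alternative chosen after seeing the data, left 12 lists with a larger spread and 12 with common variation. Scaling to the same median moved the median gene of an array by -0.08 to 0.06 (log2). Of 1585 mean signals of named genes recomputed, 52 moved by over 1 SD, nearly all where the probe sets of a gene were averaged. Signals near the background threshold limit what can be said of genes with low values.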

Other observations

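Some genes of the central nervous system list were highest in mice 1 and 6, and they stand as single values. Mobp measured 2331 in mouse 1 and 2262 in mouse 6, and 48.9 to 201 in the other 6. Mog, made by oligodendrocytes, measured 314 and 356 against at most 28.9, and the oligodendrocyte transcription factor Olig1 87 and 89.4 against at most 28.9. Gfap, an astrocyte filament gene chosen after its values were seen, measured 805 and 1292 against at most 414. The cerebellar genes Cbln1 (2433 ± 430.0) and Pcp2 (1035 ± 55.4) were not highest in both mice, and Olig2 was below background on all arrays (16.4 in mouse 1, 33.3 in mouse 6 and up to 25.2 in the others). Mbp, which both kinds of myelin contain, was highest in the same mice (9488 and 9286, others at most 7971).

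Fabp4, Lpl and Thrsp, 3 of the genes named for their large spread, were highest in mouse 5. No list of such genes was fixed, so they stand as single values. The lipoprotein lipase gene Lpl measured 2243 in mouse 5 and at most 624 in the others, and Thrsp, a regulator of lipid synthesis, 1805 and at most 465. In the epithelial list the lipid-binding protein gene Sec14l3, chosen after its values were seen, measured 2106 and at most 25.9. The interferon-stimulated gene Mx1, chosen likewise, measured 1527 in mouse 8 and at most 192 in the others. The glucocorticoid-responsive genes Tsc22d3 (483, others 1100.2 to 1625) and Zbtb16 (195, others 269 to 625), also chosen after their values were seen, were lowest in mouse 1.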
